A study of Homo sapiens with 4 samples.

How the data were processed

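RNA of A2780 and OVCAR-3 cells was measured on 4 Agilent 2-colour expression arrays, 2 per cell line. On every array the Cy5 (red) channel held RNA of vehicle-treated cells and the Cy3 (green) channel held RNA of cells of the same line given 5 µM LS-98 for 24 h, per the labels, which describe the 2 arrays of a line as biological replicates. No array carried the dyes the other way round, so an effect of the dyes on a single probe remains in the ratios of each line. It cancels in the difference between the lines as far as it is the same on all arrays. The 4 arrays lay on 1 slide and were scanned together, so there was no slide or scan batch to test.

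The spot brightness was deposited as intensity values per channel (the mean of the spot and the median of its local background), extracted with Agilent Feature Extraction 10.5.1.1, per the file headers. The files also hold processed intensity values, which that software had background-subtracted, spatially detrended and dye-normalised (linear and lowess), and their log10 ratio of red over green, per the file headers. The deposited series matrix holds log2 ratios per probe. Set against the scanner files, these were log2 of the processed green over red signal (r between 0.99995 and 0.99999, with between 99.8% and 99.9% of values within 0.01), thus treated over control, not centred further, with column medians of 0.03, -0.02, -0.02 and -0.00. They served as an alternative source of values.

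Mean spot intensities were corrected for local background by normexp with an offset of 50 and normalised within each array by loess (span 0.3), with control spots and spots marked as outliers by the extraction software at weight 0. The software had marked 327, 201, 119 and 239 such spots on the 2 A2780 and the 2 OVCAR-3 arrays, and these were left out. Spots of one probe were averaged, and 266 of 41000 probes then lacked a value on at least 1 array. The sign was set so that a positive log2 ratio means a higher signal after LS-98. Of the 41000 probes, 28737 received a current gene symbol from a RefSeq table of assembly GRCh38.p14, used for names only. Of these, 25398 were matched by the accession in the files, 280 by another RefSeq accession and 3059 by the gene name. The remaining 12263 probes kept the name in the files. Probe coordinates are those in the files (build hg18). Each gene was represented by the probe with the highest mean brightness over all arrays, which left 29969 genes or names with a value on every array. Other detected probes of the genes at the ends of each comparison are given where one moved in the opposite direction or differed by more than 1 (log2) from the chosen probe.

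A gene was tested in a line if its probe was well above background on both arrays of that line in the control channel or in the treated channel. Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per cell line over all 4 arrays, which share 1 estimate of the spread (residual degrees of freedom 2, prior degrees of freedom 3.58, prior SD 0.10). The comparisons were each line against 0 and OVCAR-3 minus A2780, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Errors written with ± are standard errors of that fit, with n = 2 arrays per line. Control levels were compared between the lines with limma on the Cy5 channel after loess and Aquantile normalisation. A probe not well above background on either array of a line in one channel gives only a bound there, written as "at least N-fold". It sets the mean of the brighter side against, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background. Gene lists (44 lists with 900 entries, of which 893 were on the array, 3 of the lists for other cell types) were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested. Each list call is given with the adjusted p obtained with an estimated correlation, and with the count of members adjusted over the list alone. With an estimated correlation camera uses at most the residual degrees of freedom, here 2, so few lists can pass whatever the correlation. The NRF2 list in A2780 had an estimated correlation of -0.02, below the preset one, yet its unadjusted camera p went from 2.41e-08 to 0.0253. A call lost in this way does not show that members vary together. fry, which tests whether the genes of a list move one way on balance, was an alternative. Unlike camera, it does not set the list against the other genes, so it can pass many lists where many genes change. Figures were drawn with matplotlib 3.10.9.

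The named genes follow a rule set before the data were examined, as were the lists, the tests and most alternatives. Per line they are the 10 genes with the largest positive and the 10 with the largest negative log2 ratio past the threshold, changed the same way on both arrays, with a gene symbol as their name in the files. For the difference between the lines they are the 8 at each end. Of each list described, up to 4 members with the smallest adjusted p are named, with any member called in the other direction. Marker genes of cell types are named from the control levels, largest differences first, and ACTB, GAPDH, TBP and HPRT1 are given as housekeeping genes.

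The steps were tested on simulated data. With spreads drawn from the fitted distribution, the fit recovered 30%, 84% and 96% of genes changed by 0.5, 1 and 2 (log2) in the A2780 comparison (22005 genes), 50%, 86% and 98% in OVCAR-3 (24081 genes) and 0%, 80% and 94% in the difference (21703 genes). False calls made up 4.35%, 6.91% and 3.30% of all calls. With each gene's moderated variance in its place, that share was 11.4%, 8.07% and 6.92%, so calls near the threshold are less certain than the threshold states. Recovery was scored on 50 changed genes per size, and most genes were simulated as unchanged. In the data 54.2% of genes were called in A2780 and 39.5% on the arrays labelled OVCAR-3. Recovery and false-call shares depend on the part of genes that change, so those given need not hold for the data. With 1 list shifted by 0.5, camera called that list and none of the other lists at the preset correlation, and 0 lists with an estimated correlation. The genes were simulated independently, so this could not show how the preset correlation performs where list members vary together. In the A2780 data the estimated correlation was 0.65 for immediate early genes and for histone genes, and -0.02 for the NRF2 list. Loess recovered a mean size of 0.97 for 200 spots changed by 1, all with the right sign. These were 200 of 43376 spots, with as many rises as falls, so loess was not tested with a change in most genes or mainly in one direction.

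The alternatives were no background correction, the processed signals of the extraction software, the series matrix values, median centring in place of loess, scaling between arrays, no filter and a stricter filter on dim probes, the mean over all probes of a gene, a replicate block, a fit on the arrays of one line, a separate-channel fit (intraspot correlation 0.43), other thresholds and leaving out each array. For the control level they also included quantile normalisation of that channel and the treated channel. The list test of the difference between the lines and a crossed pairing were added after the data were seen.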

Results

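Gene expression was profiled in A2780 and OVCAR-3, established human ovarian cancer cell lines, after 24 h with 5 µM LS-98, a compound given by its code name, or with vehicle. Each array set treated against vehicle-treated cells of one line, and each line had 2 arrays. Of 43376 probe spots per array, between 65.1% and 83.0% were well above background in the treated channel and between 74.4% and 85.7% in the control channel, and 0 were saturated. The log2 ratios of LS-98 over vehicle correlated across genes at r = 0.905 between the 2 arrays of A2780 and at r = 0.916 between those of OVCAR-3. The number of arrays limits the precision, with a median standard error of 0.07 (log2) in both lines.

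The vehicle-treated cells of the lines were compared first, because their levels bear on the cell line labels. On the arrays labelled OVCAR-3, 15 of 20 epithelial genes and 15 of 20 serous carcinoma markers were well above background on both arrays, against 13 and 12 in A2780. KRT8 and KRT18, which encode keratins of simple epithelia, the adhesion gene EPCAM, the mucin gene MUC1, the folate receptor gene FOLR1 and the transcription factor genes SOX17 and PAX8 were among them in both lines. Of all probe spots, a mean per array of 83.5% (OVCAR-3) and 76.4% (A2780) were well above background in the control channel. Fibroblast markers were above it on both arrays in 12 of 12 cases in each line. Blood cell markers were in 13 of 16 (OVCAR-3) and 10 of 16 (A2780), and endothelial markers in 5 of 10 in each. The epithelial and serous counts therefore do not set these lists apart. MUC16, which encodes a mucin used as an ovarian tumour marker and known to be made by OVCAR-3, and CDH1, the E-cadherin gene of epithelial junctions, were each measured by 1 probe, and neither was well above background on any array in the control channel. KRT7, another keratin gene, and WT1, a transcription factor used as a serous carcinoma marker, were above background on 1 of 2 arrays labelled OVCAR-3 and 0 of 2 labelled A2780. Across genes, control levels correlated at r between 0.977 and 0.979 for arrays of different labels, and at r = 0.998 within each label. No other cell line was measured to set these values against. These levels and correlations do not settle whether either label is right, so the lines are named here by the labels of the arrays. A result given for A2780 is likewise one of the arrays labelled A2780.

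Of 15 tested epithelial genes, 0 were higher and 3 were lower on the arrays labelled OVCAR-3 than on those labelled A2780, namely OCLN (-1.65 ± 0.09, adjusted p = 5.14e-05), EPCAM (-1.31 ± 0.13) and CD24 (-0.64 ± 0.10). Of 15 tested serous carcinoma markers, CRABP2 (0.61 ± 0.08) was higher and 0 were lower. Mesenchymal genes went both ways, with 11 of 19 higher and 4 lower (13 and 5 adjusted over the list alone). The calcium-binding protein gene S100A4 (4.07 ± 0.10) and the transcription factor gene SNAI2 (3.36 ± 0.13) were higher, TWIST2 was at least 25.5-fold higher, and the collagen crosslinking enzyme gene LOX was lower (-5.59 ± 0.09). Fibroblast markers likewise went both ways (8 of 12 higher and 4 lower), with POSTN (3.07 ± 0.14) and DCN (2.43 ± 0.08) higher and PDGFRA lower (-2.46 ± 0.10). Among markers of blood cells 1 of 13 was higher (TYROBP, 0.79) and 3 were lower, led by HBA1 (-3.22 ± 0.13), and among endothelial markers 1 of 5 was lower (ESAM, -0.35), or 2 adjusted over the list alone. Target genes of p53 were higher on the arrays labelled OVCAR-3 in 20 of 25 cases and lower in 1 (CCNG1, -0.37), with a median difference of 1.06 (21 and 1 adjusted over the list alone). CDKN1A, the cell cycle inhibitor p21, differed by 4.32 ± 0.08, PHLDA3 by 3.55 ± 0.08 and the stress cytokine gene GDF15 by 3.33 ± 0.08. Adjusted over the list alone, the counts of the other marker lists were the same. Several mesenchymal genes ranked high among all genes by control signal in both lines. VIM lay at percentile 99.5 in A2780 and 99.9 on the arrays labelled OVCAR-3, COL1A2 at 98.2 and 96.0, and TWIST1 at 95.2 and 93.5. MMP2 (19.6 and 20.3) and ZEB1 (41.3 and 43.7) ranked lower. KRT8 lay at 69.4 and 67.2 and EPCAM at 61.4 and 50.5. Probes of different genes are not on one scale, so these ranks are a rough guide.

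In all, 5691 of 24242 genes differed in control level at adjusted p under 0.05 in limma, 3014 higher and 2677 lower on the arrays labelled OVCAR-3, with 231 and 178 of them differing at least 4-fold. Without the second OVCAR-3 array the count was 3581.

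**Figure D1:**
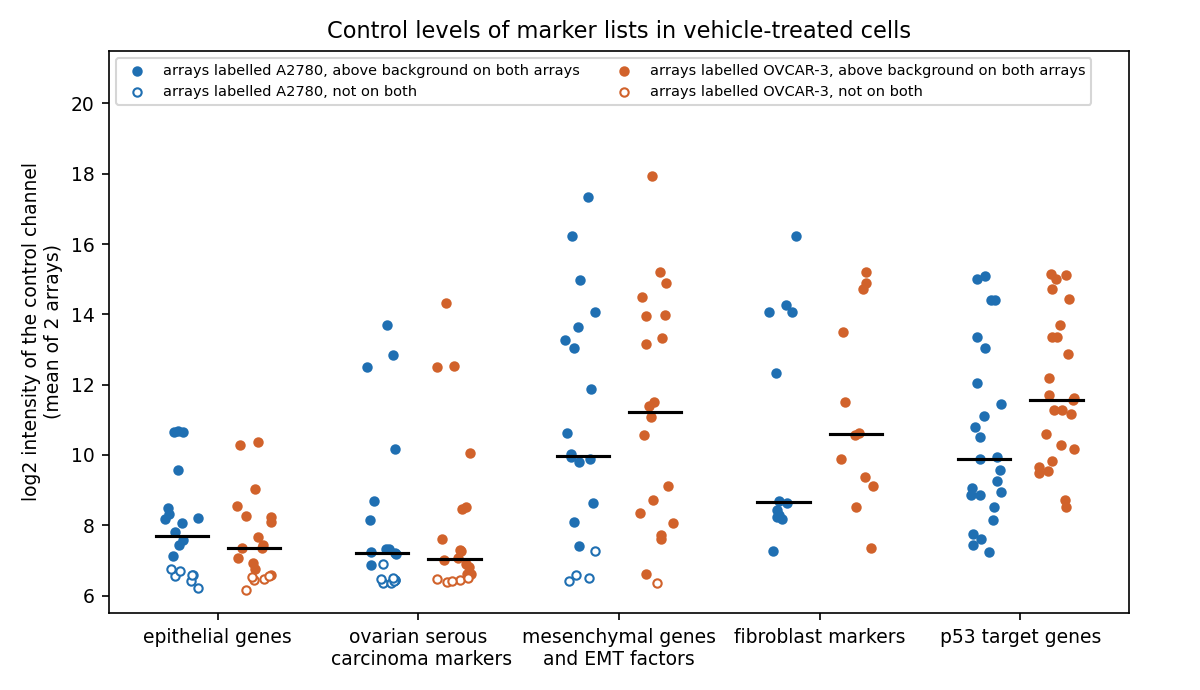
Control-channel log2 intensity of the genes of 5 lists in vehicle-treated cells, as means of 2 arrays per line. Each point is a gene, filled where its probe was well above background on both arrays of the line and open otherwise, and black bars are list medians. Levels of different probes are not on one scale, so points compare between lines and not between genes. In the p53 list, 20 of 25 genes were higher on the arrays labelled OVCAR-3.

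In A2780, the question was which transcripts changed with LS-98. SPP1, which encodes the secreted phosphoprotein osteopontin, rose 35.3-fold (log2 5.14 ± 0.13, probe on chromosome 4, 89122944 to 89123003, build hg18), and GCNA, a germ cell gene, rose 27.9-fold (4.80 ± 0.15). HMOX1, the heme-degrading enzyme heme oxygenase, rose 16.6-fold (4.06 ± 0.07, chromosome 22, 34120122 to 34120181), and GABARAPL1, a protein of autophagosome membranes, rose 13.3-fold (3.73 ± 0.06). NPTX2, TNFRSF8, HTRA3, MAL, CD24 and GDF15 rose between 10.4-fold and 11.6-fold. The largest decreases were in WFIKKN1, a secreted protease inhibitor gene, which was 6.09-fold lower (-2.61 ± 0.06, chromosome 16, 624020 to 624079), the growth factor gene FGF18 (-2.25 ± 0.07), MAP2K6, a kinase of the p38 pathway (-2.13 ± 0.05), and TET1, an enzyme that oxidises methylated cytosine (-2.10 ± 0.10). KLF15, PLPP7, NRBP2, SRCIN1, LRRC20 and SH3PXD2A fell too, by log2 values from -1.95 to -1.80. The adjusted p of these 20 genes lay between 2.73e-05 and 0.000132.

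Several lists of stress response genes rose in A2780. Lists share some members, such as ATF3 (immediate early and ATF4) and CDKN1A (p53 and histone deacetylase inhibitors), so their calls are not independent. All 26 measured immediate early genes rose (median 1.79), among them the transcription factor genes FOS (3.37 ± 0.08), EGR1 (3.27 ± 0.08) and FOSB (2.37 ± 0.06) and the mRNA decay factor gene ZFP36 (2.49 ± 0.06). The camera adjusted p of this list was 6.47e-15, and adjusted p = 0.399 with an estimated correlation. Of 23 genes of the NRF2 oxidative stress response, 16 rose and 0 fell (18 rose adjusted over the list alone), including HMOX1, the glutathione synthesis gene GCLM (2.57 ± 0.07) and the ferritin gene FTL (2.29 ± 0.06). For this list the camera adjusted p was 3.18e-07 (adjusted p = 0.384 with an estimated correlation). Of 23 genes of the unfolded protein response, 18 rose and CRELD1 fell (-0.30), or 19 and 1 adjusted over the list alone. The chaperone genes DNAJB9 (2.52 ± 0.06) and DNAJC3 (1.83 ± 0.07) and the ER degradation gene HERPUD1 (1.51 ± 0.06) led this list, with camera adjusted p = 3.18e-07 (adjusted p = 0.399 with an estimated correlation). In the ATF4 list, 19 of 30 genes rose (20 adjusted over the list alone), led by ATF3 (2.82 ± 0.08) and DDIT3 (2.17 ± 0.07), with camera adjusted p = 0.000489 (adjusted p = 0.384 with an estimated correlation). The amino acid and tRNA charging genes PSAT1, PSPH, PCK2 and AARS1 and the mTOR inhibitor gene DDIT4 fell, by values from -0.64 to -0.24. Cytosolic heat shock genes rose in 14 of 20 cases (16 adjusted over the list alone), with HSPA6 at 2.07 ± 0.09, BAG3 at 1.83 ± 0.06 and HSPA1A at 1.63 ± 0.07. The mitochondrial chaperonin genes HSPD1 (-1.09) and HSPE1 (-0.89) and the constitutive chaperone gene HSPA8 (-0.51) fell. The camera adjusted p was 0.00198 (adjusted p = 0.384 with an estimated correlation). Further probes of HSPD1 (0.14) and HSPA8 (-0.53 to 0.86) did not all fall.

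Genes of protein breakdown also rose in A2780. Of 22 proteasome subunit genes, 20 rose (median 0.41), led by PSMC4 (1.11 ± 0.06), PSMC2 (1.02 ± 0.05) and PSMD12 (1.30 ± 0.07). PSMB1 fell (-0.18) and turned positive with the processed signals, the series matrix values or the mean over probes. This gave a camera adjusted p of 8.58e-07 (adjusted p = 0.384 with an estimated correlation, and 0.132 with median centring). Of 26 autophagy and lysosome genes, 16 rose, led by GABARAPL1 and the receptor gene SQSTM1 (2.11 ± 0.06), and LAMP1 fell (-0.35), with camera adjusted p = 0.00158 (adjusted p = 0.399 with an estimated correlation). Metallothionein and metal response genes rose in 12 of 16 cases, among them MT2A (1.30 ± 0.07), with camera adjusted p = 3.27e-05 (adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell.

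Chromatin and signalling lists changed as well. Replication-dependent histone genes rose in 14 of 16 cases (median 1.18), among them H2BC12 (1.24 ± 0.06) and H2BC13 (1.21 ± 0.06), while H4C3 fell (-0.56). For this list the camera adjusted p was 3.20e-06 (adjusted p = 0.435 with an estimated correlation). Genes known to be induced by histone deacetylase inhibitors rose in 13 of 18 cases, among them CDKN1A (2.71 ± 0.06), GADD45B (2.87 ± 0.08) and CCN2 (3.02 ± 0.12). The camera adjusted p was 1.25e-05 (adjusted p = 0.384 with an estimated correlation). NF-kB and inflammatory genes rose in 11 of 19 cases, with the chemokine gene CXCL1 at 2.45 ± 0.06 and the cytokine gene LIF at 2.18 ± 0.06 (camera adjusted p = 0.000891, and adjusted p = 0.384 with an estimated correlation). FOXO target genes rose in 13 of 21 cases, with IRS2 at 2.06 ± 0.11, and CAT, RBL2 and YPEL3 fell (14 and 4 adjusted over the list alone). That list had camera adjusted p = 0.00261 (adjusted p = 0.399 with an estimated correlation). Glucocorticoid-induced genes rose in 8 of 12 cases, with the kinase gene SGK1 at 2.96 ± 0.14 (camera adjusted p = 0.00453, and adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 8 rose and 1 fell. Retinoic acid target genes rose in 9 of 12 cases (10 adjusted over the list alone), with CYP26B1 at 1.36 ± 0.08 (camera adjusted p = 0.00198, and adjusted p = 0.384 with an estimated correlation).

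Target genes of p53 went both ways in A2780. Of 25 genes, 16 rose and 7 fell, with a median of 0.26 and camera adjusted p = 0.0230 (adjusted p = 0.399 with an estimated correlation). GDF15 (3.38 ± 0.07), GADD45A (2.78 ± 0.07), CDKN1A (2.71 ± 0.06) and PLK3 (1.83 ± 0.06) rose. The DNA repair genes XPC (-0.60) and DDB2 (-0.53), the apoptosis gene BAX (-0.32) and CCNG1 (-0.70), SPATA18 (-0.40), TP53I3 (-0.32) and FDXR (-0.22) fell. Pro-apoptotic genes rose in 13 of 19 cases, led by BIK (1.77 ± 0.09), and APAF1, BAD, BAX and CYCS fell (camera adjusted p = 0.0399, and adjusted p = 0.399 with an estimated correlation). TGF-beta target genes rose in 9 of 17 cases, with BAMBI at 3.24 ± 0.07, and COL1A1 (-0.35) and SMAD6 (-0.89) fell (camera adjusted p = 0.0465, and adjusted p = 0.557 with an estimated correlation). The pro-apoptotic call ended under 4 alternatives and the TGF-beta call under 2, with adjusted p up to 0.102 and 0.0904.

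The list with the clearest decrease in A2780 was that of cytosolic ribosomal proteins, of which 28 of 30 fell (median -0.68). RPLP2 (-1.42 ± 0.08), RPS2 (-1.23 ± 0.06) and RPL10A (-1.18 ± 0.07) fell, and RPS9 rose (0.43) but was negative with median centring. This gave a camera adjusted p of 3.32e-08 (adjusted p = 0.384 with an estimated correlation). Some of these probes were very bright, with RPLP2 at a control level of 18.2 (log2). The ACTB probe, at 17.8, fell too (-1.09), while its 3 further probes gave 0.10 to 0.37. GAPDH, at 16.7, rose (0.25). Whether a dye effect on the brightest probes adds to the fall of this list was not tested beyond loess. Markers of fibroblasts, a list for another cell type, fell in 8 of 12 cases and rose in 0, with COL3A1 at -0.62 ± 0.06 and THY1 at -0.48 ± 0.06. For this list the camera adjusted p was 0.00972 (adjusted p = 0.411 with an estimated correlation, 0.0515 with median centring and 0.0566 with the mean over probes). For lists with no other count given, adjustment over the list alone left the counts in A2780 as they were.

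Of the 22005 genes tested in A2780, 11930 (54.2%) passed adjusted p under 0.05 in limma, 5843 higher and 6087 lower, of which 787 and 410 changed at least 2-fold. With median centring in place of loess, 34.5% of the calls were increases, against 49.0% with loess. At least 2-fold on both arrays, with no test, 970 genes changed.

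On the arrays labelled OVCAR-3, the same comparison was made. GDF15 rose 23.4-fold (4.55 ± 0.07, chromosome 19, 18360890 to 18360949), and the serine protease gene HTRA3 rose 13.9-fold (3.80 ± 0.07). The cancer-testis gene SPANXA1 rose 11.5-fold (3.53 ± 0.16), HMOX1 rose 11.1-fold (3.47 ± 0.07), and GABARAPL1 (3.16 ± 0.06), SPP1 (3.09 ± 0.13) and TSGA10 (3.08 ± 0.12) rose between 8.46-fold and 8.96-fold. CDKN1A (2.72 ± 0.06), EGR1 (2.61 ± 0.08) and the kinase gene PLK2 (2.60 ± 0.06) followed. The largest decreases were smaller, led by LRRC20 and the phospholipase gene PLA2G3 (both -1.85 ± 0.08), RPLP2 (-1.59 ± 0.08), PACS2 (-1.57 ± 0.10) and SCD, the desaturase of saturated fatty acids (-1.55 ± 0.06). LIPG, NPM1, MYLK, RPL22L1 and IL21R fell by values from -1.53 to -1.42. The adjusted p of these 20 genes lay between 6.52e-05 and 0.000705.

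Target genes of p53 rose in 24 of 25 cases on the arrays labelled OVCAR-3 and fell in 0 (median 1.35), with camera adjusted p = 2.61e-17 (adjusted p = 0.331 with an estimated correlation). Beside GDF15 and CDKN1A, PLK2 (2.60 ± 0.06) and the antiproliferative gene BTG2 (2.29 ± 0.07) led this list. Immediate early genes rose in 25 of 27 cases (median 0.93), with EGR1 at 2.61, ATF3 at 2.38 and FOS at 2.00, each ± 0.08 (camera adjusted p = 6.35e-14, and adjusted p = 0.387 with an estimated correlation). NRF2 response genes rose in 19 of 23 cases, among them GCLM (2.04 ± 0.07), FTL (2.03 ± 0.06) and the malic enzyme gene ME1 (1.73 ± 0.06), and the camera adjusted p was 5.12e-09 (adjusted p = 0.331 with an estimated correlation). Proteasome genes rose in 21 of 22 cases (median 0.70), with PSMD12 at 1.40 ± 0.07 and PSMC4 at 1.12 ± 0.06 (camera adjusted p = 3.51e-11, and adjusted p = 0.347 with an estimated correlation). Unfolded protein response genes rose in 14 of 23 cases, with DNAJB9 at 1.30 ± 0.06 (camera adjusted p = 1.65e-05, and adjusted p = 0.387 with an estimated correlation). Autophagy and lysosome genes rose in 17 of 26 cases (18, with 1 lower, adjusted over the list alone), with SQSTM1 at 1.92 ± 0.06 (camera adjusted p = 1.88e-05, and adjusted p = 0.365 with an estimated correlation).

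Histone genes rose in 13 of 16 cases on these arrays, with H1-2 at 1.19 ± 0.07, and H4C3 fell (-0.81), with camera adjusted p = 1.88e-05 (adjusted p = 0.479 with an estimated correlation). Genes known to be induced by histone deacetylase inhibitors rose in 15 of 18 cases, with DHRS2 at 1.16 ± 0.06 (camera adjusted p = 2.87e-07, and adjusted p = 0.365 with an estimated correlation). Metallothionein and metal response genes rose in 12 of 15 cases, with the zinc exporter gene SLC30A1 at 1.22 ± 0.08, and MT1F fell (-0.29), with camera adjusted p = 3.82e-05 (adjusted p = 0.387 with an estimated correlation). FOXO target genes rose in 13 of 21 cases (14 adjusted over the list alone), led by TOB1 (1.12 ± 0.07), and CAT, RBL2, SELENOP and YPEL3 fell, with camera adjusted p = 0.00197 (adjusted p = 0.387 with an estimated correlation). NF-kB and inflammatory genes rose in 8 of 17 cases (9 adjusted over the list alone), with LIF at 1.14 ± 0.06, although a further LIF probe gave -0.06 (camera adjusted p = 0.00326, and adjusted p = 0.387 with an estimated correlation). Glucocorticoid-induced genes rose in 6 of 12 cases (7 adjusted over the list alone), with SGK1 at 1.61 ± 0.14, and FKBP5 fell (-0.49), with camera adjusted p = 0.0126 (adjusted p = 0.387 with an estimated correlation).

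Lipid, nucleotide and DNA metabolism genes fell on the arrays labelled OVCAR-3. Of 24 cholesterol synthesis genes, 18 fell and 0 rose (19 fell adjusted over the list alone), with a median of -0.50. The sterol reductase gene DHCR7 (-1.21 ± 0.06), the lanosterol synthase gene LSS (-1.19 ± 0.06) and the kinase gene MVK (-0.87 ± 0.06) led, with camera adjusted p = 2.69e-08 (adjusted p = 0.331 with an estimated correlation). In fatty acid synthesis and desaturation, 8 of 15 genes fell (10 adjusted over the list alone), led by SCD and the desaturase gene FADS1 (-1.11 ± 0.06), and ME1, ACACA (0.42) and ACSL1 (0.36) rose. That list had camera adjusted p = 0.0136 (adjusted p = 0.387 with an estimated correlation). Of 28 DNA replication genes, 16 fell (18 adjusted over the list alone), with E2F1 at -0.92 ± 0.05 and MCM6 at -0.85 ± 0.06, and PCNA (0.58), RRM2 (0.58), ORC1 (0.32) and RRM1 (0.26) rose. The camera adjusted p was 9.35e-05 (adjusted p = 0.387 with an estimated correlation), and RRM1 was negative with median centring. Of 20 homologous recombination genes, 13 fell, with BRCA1 at -0.73 ± 0.07 and FANCD2 at -0.55 ± 0.06, and RAD51C rose (0.52). Adjusted over the list alone, 14 fell and 3 rose, and the camera adjusted p was 0.00289 (adjusted p = 0.387 with an estimated correlation). Nucleotide synthesis genes fell in 11 of 20 cases (16 adjusted over the list alone), with CAD at -0.72 ± 0.06, and RRM1, RRM2 and UMPS (0.27, negative with median centring) rose. That list had camera adjusted p = 0.00207 (adjusted p = 0.387 with an estimated correlation).

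Glycolysis genes fell in 11 of 21 cases on these arrays (12 adjusted over the list alone), with LDHA at -1.13 ± 0.06 and HK2 at -0.81 ± 0.06. ALDOA (0.43), GAPDH (0.36) and ENO2 (0.31) rose, of which ALDOA and GAPDH were negative with median centring. This gave a camera adjusted p of 0.0222 (adjusted p = 0.521 with an estimated correlation), and the call ended with the processed signals (0.243), the series matrix values (0.237) and without the first OVCAR-3 array (0.105). Cytosolic ribosomal protein genes fell in 22 of 30 cases (25, with 2 higher, adjusted over the list alone), with a median of -0.53. RPLP2 (-1.59 ± 0.08) and RPL10A (-1.26 ± 0.07) fell, RPS9 rose (0.52), and the camera adjusted p was 5.06e-09 (adjusted p = 0.365 with an estimated correlation). The limit given for bright probes of this list in A2780 holds here too. Fibroblast markers fell in 8 of 12 cases (10 adjusted over the list alone), with PDGFRB at -0.56 ± 0.06 (camera adjusted p = 0.00125, and adjusted p = 0.387 with an estimated correlation). For lists with no other count given, adjustment over the list alone left the counts as they were.

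Of the 24081 genes tested on the arrays labelled OVCAR-3, 9520 (39.5%) passed in limma, 4883 higher and 4637 lower, of which 359 and 124 changed at least 2-fold. With median centring 5701 genes passed, 34.5% of them increases against 51.3% with loess, and without the first or the second OVCAR-3 array 3769 or 3645 passed.

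**Figure D2:**
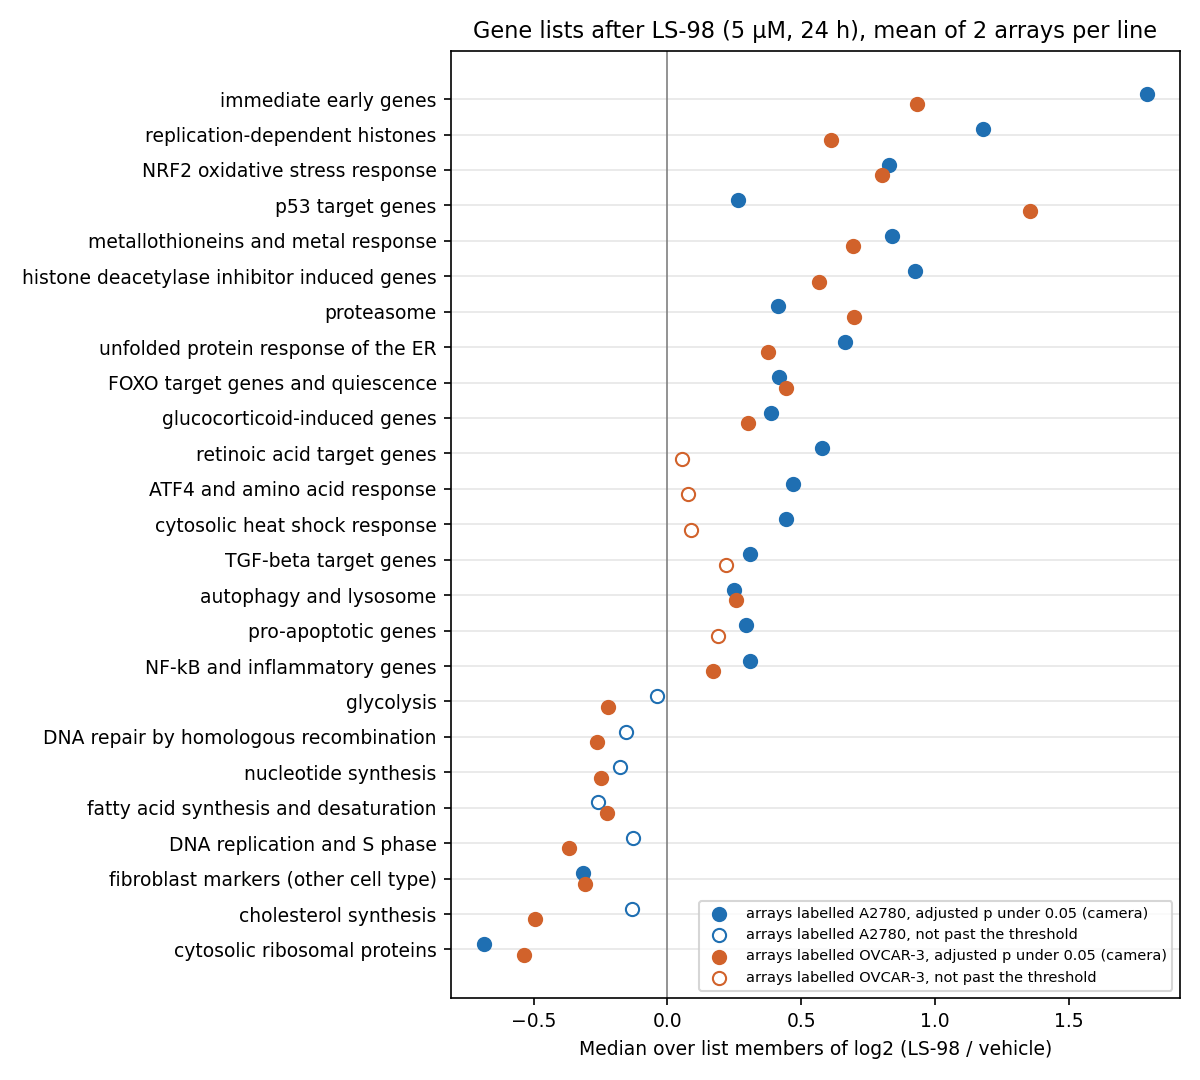
Median log2 ratio of LS-98 over vehicle over the members of each list, for the lists with camera adjusted p under 0.05 in at least 1 line, as means of 2 arrays per line. Filled points passed that threshold in the line and open points did not. Immediate early genes had the highest median in A2780 (1.79), p53 target genes had the highest median on the arrays labelled OVCAR-3 (1.35), and ribosomal protein genes had the lowest in both (-0.68 and -0.53).

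Across genes the responses of the lines ran together. Of 21703 genes tested in both lines, 3733 rose in both and 3608 fell in both, where independent lists of these sizes would share 1243 and 1251. In 208 genes the calls were opposite, where 2498 would be by the same reckoning. HMOX1, GABARAPL1, SPP1, GDF15, HTRA3 and CDKN1A rose and LRRC20, PLA2G3, RPLP2, NPM1 and MYLK fell in both lines. The log2 ratios correlated at r = 0.805 (Spearman's rho 0.777) across genes, which are not independent replicates, and at r between 0.744 and 0.804 between single arrays of different lines. Of 44 lists, camera called 19 in A2780 and 20 on the arrays labelled OVCAR-3, and 0 in either line with an estimated correlation. The estimated form rests on 2 residual degrees of freedom, so its count does not show that list members vary together. The lines share no control RNA, but all arrays share the dye orientation. With median centring 4568 genes were called the same way in both lines, 30.8% of them increases against 50.9% with loess, and without the first or the second OVCAR-3 array 3095 or 3231 were.

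The difference of the responses was tested directly as OVCAR-3 minus A2780. SPANXA1 (2.67 ± 0.23), TSGA10 (2.71 ± 0.17), the homeobox gene OTP (2.03 ± 0.09), the sulfatase gene SULF2 (2.28 ± 0.09) and the p53 targets PHLDA3 (2.28 ± 0.08) and FAS (2.04 ± 0.11) had higher values on the arrays labelled OVCAR-3, where each rose. In A2780, SPANXA1 was not well above background in vehicle-treated cells and rose at least 1.79-fold, so the size of its difference is uncertain. WFIKKN1 fell in both lines and less on the arrays labelled OVCAR-3 (1.93 ± 0.09), and the ubiquitin ligase gene TRIM2 fell in A2780 (-1.57) and rose on the arrays labelled OVCAR-3 (0.38), a difference of 1.95 ± 0.11. The membrane protein gene MAL (-3.10 ± 0.15), the receptor gene TNFRSF8 (-3.06 ± 0.09), GCNA (-2.98 ± 0.21), RASD1 (-2.65 ± 0.08), CD24 (-2.47 ± 0.14), ARSI (-2.31 ± 0.11), ARL14 (-2.23 ± 0.09) and BAMBI (-2.18 ± 0.09) had lower values on the arrays labelled OVCAR-3, each after a rise in A2780. The adjusted p of these 16 differences lay between 0.00157 and 0.0071.

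By list, p53 target genes had higher values on the arrays labelled OVCAR-3 and several stress lists had lower ones, while the NRF2 list (camera adjusted p = 0.165) and the autophagy and lysosome list (0.526) were not called. Of 25 p53 targets, 20 had a higher value on the arrays labelled OVCAR-3 (21 adjusted over the list alone), led by PHLDA3, FAS, FDXR (1.92 ± 0.10) and DDB2 (1.71 ± 0.10), and GADD45A had a lower one (-0.78). The median difference was 0.97, with camera adjusted p = 1.44e-15 (adjusted p = 0.346 with an estimated correlation). Immediate early genes had lower values there in 17 of 26 cases (23 adjusted over the list alone), with a median of -0.85 and FOSB at -1.43 ± 0.08 (camera adjusted p = 9.29e-17, and adjusted p = 0.402 with an estimated correlation). Values of the ATF4 list were lower in 14 of 30 cases, with CEBPB at -0.89 ± 0.08, and DDIT4 was higher (0.65), or 22 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.53e-07, and adjusted p = 0.346 with an estimated correlation). The unfolded protein response was lower in 8 of 23 cases (10 adjusted over the list alone), with HERPUD1 at -1.24 ± 0.08 (camera adjusted p = 8.27e-05, and adjusted p = 0.440 with an estimated correlation). Heat shock genes were lower in 8 of 20 cases (13 adjusted over the list alone), with HSPA1A at -1.61 ± 0.11 and BAG3 at -1.07 ± 0.09 (camera adjusted p = 3.38e-06, and adjusted p = 0.346 with an estimated correlation). Cholesterol synthesis genes were lower in 11 of 24 cases (15 adjusted over the list alone), with INSIG1 at -1.04 ± 0.08 and IDI1 at -0.78 ± 0.09 (camera adjusted p = 7.99e-08, and adjusted p = 0.346 with an estimated correlation).

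In all, the responses of 2464 of 21703 genes differed at adjusted p under 0.05 in limma, 1338 higher and 1126 lower on the arrays labelled OVCAR-3. This count depended on the processing, at 22 with the processed signals (27.3% higher, against 54.3%), 0 with the series matrix values (5145 at unadjusted p under 0.05), 433 with median centring, 1508 with scaling between arrays and 1123 with a replicate block. It was 56 without the first and 33 without the second OVCAR-3 array, and in these fits the lone array was assumed to vary like the others.

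**Figure D3:**
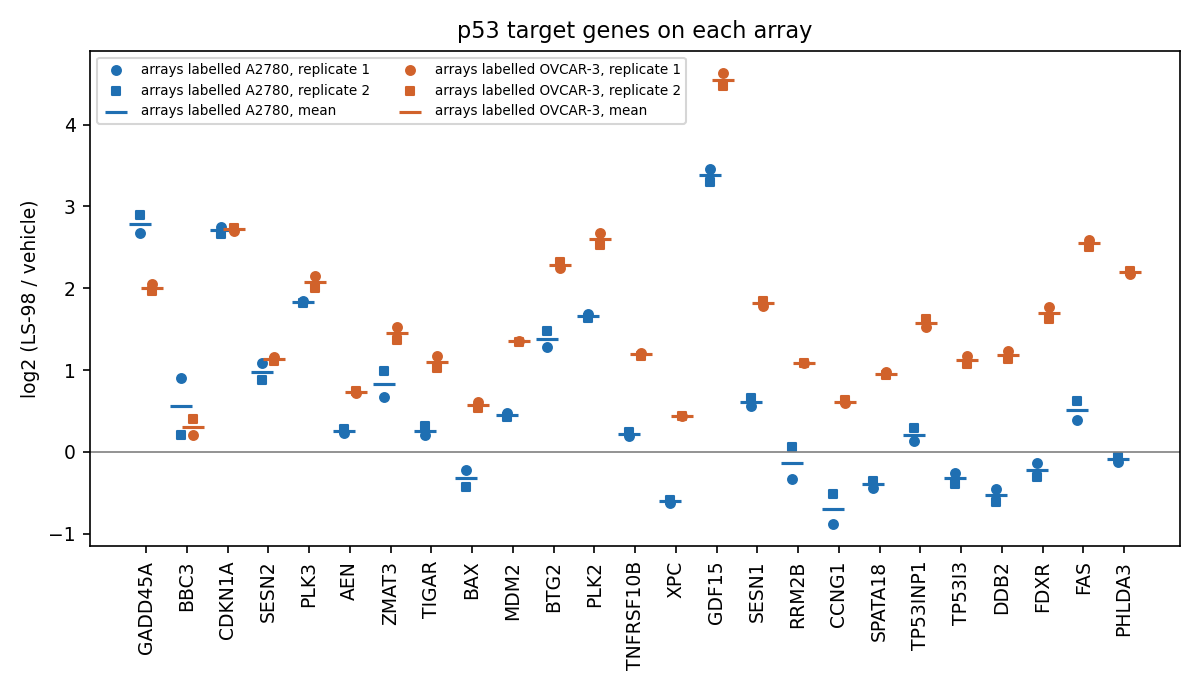
Log2 ratio of LS-98 over vehicle for 25 p53 target genes, ordered by the difference between the lines. Circles and squares are the 2 arrays of a line, drawn in one colour per line, and horizontal marks are their mean. On the arrays labelled OVCAR-3 24 genes rose, while in A2780 16 rose and 7 fell.

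Housekeeping genes were not all steady. ACTB, the beta-actin gene, was lower after LS-98 in A2780 (-1.09 ± 0.09) and on the arrays labelled OVCAR-3 (-1.36 ± 0.09), but its 3 further probes gave values from 0.10 to 0.37 and from -0.03 to 0.14. GAPDH gave 0.25 ± 0.07 and 0.36 ± 0.07, and turned to -0.30 and -0.18 with median centring. TBP gave 0.41 ± 0.06 and 0.22 ± 0.06. HPRT1 gave -0.10 ± 0.06 in A2780 (adjusted p = 0.175) and -0.37 ± 0.06 on the arrays labelled OVCAR-3.

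Probes of one gene did not always move together. Of 47 named genes, 20 had a further detected probe, and in 5 of these (ACTB, NPM1, PLA2G3, SCD and SRCIN1) one moved in the opposite direction in at least 1 line. In A2780 and on the arrays labelled OVCAR-3 these probes gave -0.82 to 0.16 and -0.89 to 0.16 for NPM1, 0.11 and -0.63 for PLA2G3, up to 0.80 and up to 0.18 for SCD, and -0.77 to 0.32 and -1.19 to 0.09 for SRCIN1. Smaller changes than with the chosen probe came from single further probes of MAP2K6 (-1.07 and -1.06), SH3PXD2A (-0.76 and -0.18), RASD1 (1.62 and 0.06) and PACS2 (-0.50 and -0.40). A further probe of HTRA3 gave 0.63 in A2780 and 0.23 on the arrays labelled OVCAR-3, one of LRRC20 gave -0.18 on the latter, one of CDKN1A gave 0.91 in A2780, and 5 of RPS2 ranged from -1.34 to 0.36 in A2780. A further probe of EDEM1 gave -0.16 on the arrays labelled OVCAR-3, and one of MTF1 gave -0.10 in A2780. Values of metallothionein, HSPA1A, histone, tubulin, ribosomal protein, SPANXA1 and CD24 probes are uncertain, because near-identical copies can bind the same probe.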

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

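The tests below of the hybridisation, of exchanged labels and of the p53 targets in vehicle-treated cells were chosen after the values they bear on were seen, and that of dim spots before.

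The responses of 2464 genes differed between the lines. Of the genes named for one line, GDF15 (1.17) and PLK2 (0.94) rose more on the arrays labelled OVCAR-3, and PLPP7 (1.23), FGF18 (1.22), TET1 (1.11), KLF15 (0.97), SH3PXD2A (0.96), MAP2K6 (0.87), NRBP2 (0.69) and SRCIN1 (0.60) fell less there. Their further probes did not all do so. Those of MAP2K6 (-1.07 in A2780 and -1.06 on the arrays labelled OVCAR-3) and SRCIN1 (from -0.77 to 0.32 and from -1.19 to 0.09) did not. Those of FGF18 (-1.78 and -0.74), TET1 (-2.06 and -0.98), SH3PXD2A (-0.76 and -0.18) and NRBP2 (-1.13 and -0.87) also fell less on the arrays labelled OVCAR-3. SPP1 (-2.05) and NPTX2 (-2.07) rose less on those arrays, and LIPG (-1.89) rose in A2780 and fell there. GABARAPL1 (-0.57), HMOX1 (-0.59) and EGR1 (-0.66) rose less there but had the opposite sign of difference with scaling between arrays. At the ends of the range stood TSGA10 (2.71), SPANXA1 (2.67), PHLDA3 (2.28), SULF2 (2.28), FAS (2.04), OTP (2.03), TRIM2 (1.95) and WFIKKN1 (1.93) on one side, and MAL (-3.10), TNFRSF8 (-3.06), GCNA (-2.98), RASD1 (-2.65), CD24 (-2.47), ARSI (-2.31), ARL14 (-2.23) and BAMBI (-2.18) on the other.

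The genes of the p53 target list rose far more widely on the arrays labelled OVCAR-3 than in A2780. A dye effect alike on all arrays cancels in this difference by design, and one that differed between arrays was not tested. A compression of dim spots would leave little difference in bright ones. The 20 members brighter in control A2780 cells than the median gene there had a median of 0.95, which excludes it as the whole account. The 5 dimmer members had a median of 1.35, so a part of it in their values is not excluded. If this pathway was already active in the cells on the arrays labelled OVCAR-3, its targets would stand higher there before treatment too, and 20 of 25 did, which fits. RNA of another line under the label OVCAR-3, for which these values would not describe that line, and a biological difference between the lines of another kind remain open and were not tested.

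On the arrays labelled OVCAR-3 MUC16 and CDH1 were not above background, although 15 of 20 epithelial genes and 15 of 20 serous carcinoma markers were. These counts are no higher a share than that of all probe spots. A weak hybridisation would leave fewer spots above background, but 83.5% were in the control channel of the arrays labelled OVCAR-3 against 76.4% for A2780. This does not exclude it, because the share of dim spots past the flag varied with the array. Of 320 spots of E1A control probes, with median signals of 96.3 to 124, 166 and 226 passed in that channel on the arrays labelled A2780. On those labelled OVCAR-3, 270 and 244 did. An exchange of the labels of the lines would put these transcripts on the arrays labelled A2780, but 0 of these genes were above background there. An exchange alone therefore does not account for their absence. Each gene had 1 probe, and a failing probe would read this way under either labelling, so an exchange itself is not excluded. Probes that fail, RNA of another line and altered marker expression in a stock of the named line remain open and were not tested.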

How the results depend on the processing

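The crossed pairing of replicates and the list test of the difference were added after the results were seen, and all other alternatives were set before. The cause of each move below was not tested.

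In A2780, 970 genes changed at least 2-fold on both arrays with no test (67.4% of them increases), against 11930 called. On the arrays labelled OVCAR-3, 5701 genes passed with median centring, 5574 at adjusted p under 0.01 and 393 changed at least 2-fold on both arrays (75.6% of them increases), against 9520, and leaving out 1 array gave 3645 to 11467. GAPDH reversed with median centring, to -0.30 in A2780 and -0.18 on the arrays labelled OVCAR-3.

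For the difference between the lines, against 2464, the count was 22 with the processed signals, 0 with the series matrix values, 433 with median centring, 1508 with scaling between arrays, 247 at adjusted p under 0.01, 114 for at least 2-fold, and 33 to 3689 with 1 array left out. With the replicate block it was 1123, and the block gave 10941 in A2780, 8133 on the arrays labelled OVCAR-3 and 6291 the same way in both lines.

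The genes changed the same way numbered 4568 with median centring, 4437 at adjusted p under 0.01, 264 at least 2-fold, and 3095 to 7551 with 1 array left out, against 7341. The correlation of the lines was 0.765 with the processed signals and with the series matrix values, 0.772 with no filter, and 0.769 to 0.802 with 1 array left out, against 0.805.

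The lists called in A2780 numbered 0 with an estimated correlation and 36 with fry, against 19, those on the arrays labelled OVCAR-3 0 and 35, against 20, and those of the difference 0 with an estimated correlation, against 24. Control levels differed in 3581 to 5957 genes with 1 array left out, against 5691.

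The pairing of replicates by number left deviations with r = -0.118, and a crossed pairing gave 12405, 9946 and 2629 genes. Of 889 alternatives for single named genes, 843 held, 43 were weaker, 1 was stronger and 2 reversed.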

Other observations

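The difference between the lines was tested on lists after the lists of each line had been seen, as was the test on base composition, while those on further probes were set before.

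Several smaller sets also differed between the lines, although with an estimated correlation no list of the difference passed (lowest adjusted p = 0.346). Hypoxia target genes had lower values on the arrays labelled OVCAR-3 in 7 of 21 cases (10, with 2 higher, adjusted over the list alone), led by the peptide hormone gene ADM (-2.11) and the clock repressor gene BHLHE40 (-1.21), while DDIT4 was higher (0.65), with camera adjusted p = 0.000824. The carbonic anhydrase gene CA12 (-0.82) and the transcription factor gene EGR3 (-0.88) were lower among estrogen-induced genes, 4 of 14, with camera adjusted p = 0.000406. In the retinoic acid list LRAT (-0.85), STRA6 (-0.69) and CRABP2 (-0.60) were lower. The chemokine gene CXCL1 (-2.09) and the cytokine gene LIF (-1.04) were lower among NF-kB genes, 3 of 16, with camera adjusted p = 0.0133, a call that ended with scaling between arrays (0.0811). Among genes known to be induced by histone deacetylase inhibitors, GADD45B (-2.17) and CCN2 (-1.22) were lower, a list call that ended with scaling between arrays too (0.405). Histone genes were lower in 6 of 16 cases (12 adjusted over the list alone), with H2BC11 at -0.67 and H2AC8 at -0.64, a list call that ended with fry (0.102). The proteasome list was called higher on the arrays labelled OVCAR-3 (median 0.14, camera adjusted p = 0.00372), with PSMD1 and PSMA4 (0.36) the only called members of 22 and 0 adjusted over the list alone, and this ended with median centring (0.0631). The mitosis list was called higher too (camera adjusted p = 0.0402), with PLK1 (0.37) called of 31 and 0 adjusted over the list alone, and this ended with the processed signals (0.0887), median centring (0.0607) and fry (0.312), among others. The neuronal tubulin genes TUBB2B (-1.92) and TUBB3 (-0.70) were lower, and the receptor kinase gene AXL was higher. Of 22 actin and MRTF or YAP target genes 4 were lower and 1 was higher. That list was called lower (camera adjusted p = 0.0135), a call that did not hold under every alternative.

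In A2780 some lists with many changed genes were called only under alternatives. Of these, fry does not set a list against the other genes, and it passed 36 of 44 lists in A2780 and 35 on the arrays labelled OVCAR-3. Of 31 mitosis genes 14 fell and 4 rose (camera adjusted p = 0.0503), and the list was called lower with the replicate block (0.0431), no filter (0.0195) and median centring (0.000795), among others. Of 28 DNA replication genes 13 fell and 6 rose (0.198, and 0.0154 with median centring and 0.0313 with fry), and of 24 cholesterol synthesis genes 10 fell and 5 rose (0.250, and 0.00732 with fry). On the arrays labelled OVCAR-3 the ATF4 list was split, with 12 of 30 higher and 11 lower (0.313, and 0.00263 with fry). The replication genes RRM2 (-0.96) and CDC6 (-0.69) had lower values there than in A2780, and PCNA (0.50) and RFC4 (0.69) had higher ones.

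The lines shared most of their response, and all arrays carried the dyes the same way. If a dye effect of single probes lay behind the shared calls, further probes of the same genes would often disagree in both lines, and of 3397 such probes 67.5% had the same sign in both lines and 18.8% the opposite sign in both, which cannot tell a partial dye effect from none. Of the 264 genes changed at least 2-fold the same way on all arrays, 94 had further probes, 137 in number. Of these probes 113 (82.5%) had the same sign in both lines and 16 the opposite sign in both. This argues against a dye effect as the only source of the direction for most of these probes. Signs cannot exclude a dye effect on the size of a change. A further probe of HTRA3 gave 0.63 in A2780 and 0.23 on the arrays labelled OVCAR-3, where the chosen probe gave 3.45 and 3.80. Genes with no further probe remain open. A smooth trend with base composition took up at most 0.973% of the variance of the responses, which excludes it as the source of their correlation (0.805), and a trend with brightness was not tested beyond its removal by loess. A response to LS-98 shared by the lines remains open as an account of the rest, and was not tested by a dye swap.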
